A study of Homo sapiens with 6 samples.

How the data were processed

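RNA was sequenced from Raji, a Burkitt lymphoma cell line, and from Raji/253R, its APTO-253-resistant subline, with 3 RNA samples per line. Per the study record, total RNA was isolated with a column kit, poly(A)-selected and made into libraries with an Illumina TruSeq kit; whether the libraries kept strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The labels call the samples of a line independent and do not say whether they came from separate cultures, so p-values measure the spread between these samples. The submitters' processing notes name FastQC 0.11.4, Subread and featureCounts 1.5.0-p1, edgeR and limma. The genome build and annotation are not given in the sources used here.

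The main table gives log2 values per gene and library, which the authors made from read counts per gene; the deposited log2 values are log2 CPM (reads scaled to a common library size) with an offset of 0.5 reads and effective library sizes that differ from the read totals. This form was tested on the file: with each library's effective size taken from its genes at 0 reads, 99.999% of 104346 values came out as whole reads within 0.01 reads. The exception is KEL in parental replicate a, listed as exactly 0, where the other parental values are -1.63 and -1.74 and the authors' fold implies about -1.77. Computing limma-voom on the recovered reads gave 3498 genes under an adjusted p of 0.05, all of them also called in the authors' deposited table. The smallest number of reads per gene over the 6 libraries was 51, so genes below some count were left out before deposit. The same table holds a fold ratio and p-values with FDR-adjusted values made by the authors, per the file headers, for Raji/253R against parental Raji. Further deposited sheets give subsets of this table (ABC family, top genes, a curated list of genes higher by at least 2-fold, replication and repair, DNA repair) and the authors' gene ontology and pathway terms with FDR values; how the terms were tested is not given in the sources used here. Values taken from these are named as the authors' where printed. 3 symbols carry an added name, such as CDKN1B (p27), and were kept as written.

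Because the deposited unit is log2 and not counts, the main test was limma (3.58.1, in R 4.3.3): a linear model of the log2 values as deposited for all 17391 genes, with the line as the only term, and empirical Bayes variances with a mean-variance trend. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and those with an absolute log2 difference of at least 1 counted as at least 2-fold. For genes with few reads, a fold from log2 values with an offset can lie below or above the ratio of reads. Recovered reads are therefore given for named genes with 30 reads or fewer in a line. Beside them stands the ratio of the summed reads scaled by library size, with its exact (Clopper-Pearson) 95% interval. A line with 0 reads was given a floor of 3 reads over its libraries. PCR copies are not independent molecules, so intervals and floors cover counting error only. Tests for count data in edgeR or DESeq2, foreseen for a table of counts, were not run.

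Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 40 lists of at least 3 measured genes out of 41 fixed lists, and beside each list stand the counts over all genes and adjusted over the list alone. The replication and repair count joins 8 lists. The lists, the tests and the rule for the genes named were fixed before the data were examined. The rule takes the 8 highest and 8 lowest differences among called genes with a mean log2 CPM of at least 1; ABCG2, ABCB1, ABCC1, MYC, KLF4, CDKN1A, BRCA1 and BRCA2 whatever their result; up to 4 members of smallest p from each list described; up to 6 ABC family genes; and up to 4 genes or terms of smallest p from each authors' sheet. Some items that the rule or the lists cover are not reported here. Genes were matched by symbol and then by Ensembl identifier. Chromosome, gene type, gene order, GC content and transcript length come from GENCODE 29 by Ensembl identifier, which matched 97.4% of the genes; since the authors' build is unknown, no coordinates are given. 11 symbols stand for more than 1 identifier.

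Samples were assigned from the labels' titles and descriptions, and the table's columns carry the names the labels give. No replicate pair was a duplicate: a chi-square over genes of recovered reads was between 42.8 and 116 per degree of freedom for every pair within a line. Both lines use the letters a, b and c, and no source says what a letter shares. After centring each gene within its line, same-letter libraries correlated at 0.352 (a), 0.253 (b) and 0.244 (c) over 12071 genes of mean log2 CPM above 1, while the correlations across letters were between -0.290 and -0.0624. The letters were taken to pair the samples as a working assumption, and a fit with the letter as a block was set beside the main one. Printed p-values and standard errors are from the main fit, without the block, unless the block is named.

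Alternatives were quantile normalization, median-centred libraries, minimum mean log2 CPM of 1 and of 3, no variance trend, a robust prior, array weights, each library left out, the block, a threshold of 0.01, Holm adjustment, treat against 2-fold, an estimated correlation in camera, and fry. Chosen after seeing the data were voom weights on recovered reads, the authors' own test, leaving out genes of chromosomes 4 and 13, and protein-coding genes only. The fit was tested on simulated data: reads drawn for the 17391 genes with 50 genes changed at each of 4 fold sizes, in the comparison of Raji/253R with parental Raji, gave calls for 30% of genes changed 1.5-fold, 86% of those changed 2-fold and 98% of those changed 4-fold and 8-fold, with 6 calls among unchanged genes. With 1 list shifted by -0.5 among the 40 simulated lists 2 were called, and with nothing shifted 0 were called; simulated genes were independent of each other, which real genes are not. A shift of 0.5 planted on chromosome 13 was recovered as 0.51 over 9690 genes. Plots were drawn with matplotlib 3.10.9.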

Results

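Gene expression was measured by RNA-seq in Raji, an Epstein-Barr virus-positive Burkitt lymphoma cell line, and in Raji/253R, a subline grown for 6 months in rising concentrations of the experimental anticancer compound APTO-253 until it was resistant. Each line was represented by 3 RNA samples that the labels call independent, lettered a, b and c in both lines, and the comparison asks which genes differ between the resistant subline and its parent. Only 1 resistant subline was sampled, so the spread between its 3 libraries is that of RNA samples of that subline. The table used here gives log2 CPM, read counts scaled to a common library size, for 17391 genes. Read counts recovered from those values summed to 41710671, 41843310 and 39265667 reads in parental replicates a, b and c and to 41639668, 42329604 and 45275597 reads in Raji/253R replicates a, b and c. Values are given as the mean of log2 CPM ± SD with n = 3 per line, and differences are Raji/253R minus parental Raji on the log2 scale with the standard error (SE) from the limma fit.

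The resistant subline differed from its parent in many genes: 3535, or 20.3% of those tested, had a Benjamini-Hochberg adjusted p under 0.05 by limma, of which 1850 were higher and 1685 lower in Raji/253R. At least 2-fold differences were found for 1725 of them, 1019 higher and 706 lower. Genes rising most included chemokine and surface receptor genes and the drug efflux gene ABCG2, and genes falling included a large part of the DNA replication machinery. The first principal component carried 68.5% of the variance and separated the lines, with parental libraries between -70.4 and -49.6 and Raji/253R libraries a, b and c at 60.8, 70.7 and 39.3. The 3 values of one line lay entirely above those of the other for 6743 genes, 38.8% of those tested. Chance gives 10% if the libraries are freely exchangeable, a share that ignores the letters common to both lines. The authors' deposited table lists 3498 genes under the same threshold, and 3459 genes were called by both. The count depended on single libraries: it was 2020 without parental replicate b, 2023 without parental replicate c, 1523 without Raji/253R replicate a and 1687 without Raji/253R replicate b. Higher and lower genes then numbered 1228 and 792, 1161 and 862, 902 and 621, and 943 and 744, in the same order of libraries left out. The count of called genes rose to 4069 without parental replicate a and to 4680 without Raji/253R replicate c. Without Raji/253R replicate a the count of genes with at least 2-fold difference was 1079, and without Raji/253R replicate b it was 1105.

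Among genes with a mean log2 CPM of at least 1, the 8 with the highest differences were CTA-941F9.9, IL32, CLEC4A, MPEG1, FCRL5, CCL3, IL1R2 and ITGAX. IL32, a cytokine gene, rose from 0.23 ± 0.91 to 4.76 ± 0.74 (difference 4.52, SE 0.46, adjusted p = 0.000256). CLEC4A, a C-type lectin receptor gene, rose by 4.24 (SE 0.35), and MPEG1, which encodes a pore-forming protein of phagocytes, rose from 1.02 ± 0.21 to 5.19 ± 0.62. FCRL5, an Fc receptor-like gene of B cells, rose by 4.05 (SE 0.33). The chemokine gene CCL3 rose by 3.85 (SE 0.42), the decoy receptor gene IL1R2 by 3.84 (SE 0.53) and the integrin gene ITGAX by 3.79 (SE 0.43). These 8 calls held under every alternative fit at the 0.05 threshold in which the gene was tested, with Benjamini-Hochberg adjusted p at or below 0.0156. Holm adjustment, which called far fewer genes, is not counted among these fits.

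The 8 lowest were STS, ZDHHC21, KLHL9, SPARCL1, IGHV3-38, RPPH1, RMRP and SHANK2. STS, which encodes steroid sulfatase, fell from 6.39 ± 0.11 to -3.94 ± 0.22 (difference -10.33, SE 0.22, adjusted p = 6.04e-09). In reads this was 10382 over the 3 parental libraries against 7 over the 3 Raji/253R libraries, a 1547-fold higher level in the parent after scaling to library size (95% exact interval 751 to 3849, counting error only). ZDHHC21, a palmitoyltransferase gene, fell from 3.94 ± 0.34 to -1.02 ± 0.56, and KLHL9, a ubiquitin ligase adaptor gene, fell from 4.23 ± 0.33 to 0.13 ± 0.30. SPARCL1 had a difference of -3.80 (SE 0.35) and SHANK2 one of -3.24 (SE 0.38). IGHV3-38, an immunoglobulin heavy chain variable segment that shares sequence with others of its family, had a difference of -3.77 (SE 0.21). RPPH1 and RMRP, the RNA components of RNase P and RNase MRP, had differences of -3.32 (SE 0.36) and -3.29 (SE 0.47). Both RNAs lack a poly(A) tail, and other RNAs without one were also lower in the Raji/253R libraries, among them RN7SK with a difference of -2.78 and RN7SL1 with one of -2.42, which were chosen after their values were seen.

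**Figure D1:**
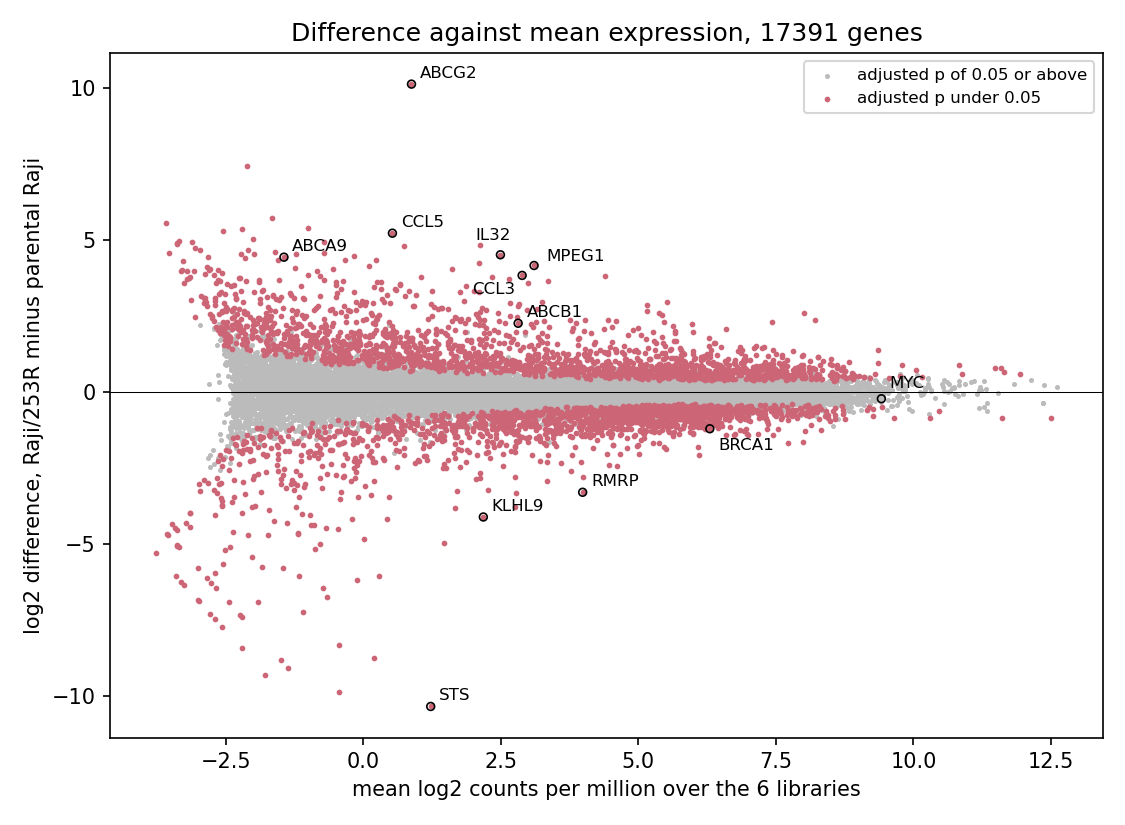
Each point is 1 of the 17391 genes, placed by its mean log2 CPM over the 6 libraries (horizontal axis) and its log2 difference, Raji/253R minus parental Raji (vertical axis), with the 3535 genes of adjusted p under 0.05 in red and 12 circled genes named. ABCG2 lies at 10.14 and STS at -10.33, and MYC lies near 0 at -0.21.

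ABC transporters, the family that includes the main drug efflux pumps, were examined because the study lists this family on a sheet of its own. Of 31 family members measured, 11 rose, 3 fell and 17 did not pass the test. Adjusted over the list alone, 13 rose and 4 fell. ABCG2, a drug efflux pump gene (ENSG00000118777, chromosome 4), rose from -4.19 ± 1.85 to 5.95 ± 0.16 (difference 10.14, SE 0.71, adjusted p = 3.17e-05). It had 6, 3 and 0 reads in the parental libraries and 2298, 2869 and 2808 in the Raji/253R libraries, an 849-fold higher level in Raji/253R after scaling to library size (95% exact interval 447 to 1858, counting error only). The ratio of reads was 1661 without parental replicate a, and the log2 difference of ABCG2 was 10.87 without that library and 9.10 without parental replicate c, the library with 0 reads. The authors' deposited table gives a fold of 1127 for ABCG2 with an adjusted p of 2.24e-05. ABCB1, which encodes P-glycoprotein, rose from 1.68 ± 0.22 to 3.95 ± 0.49 (difference 2.27, SE 0.25, adjusted p = 0.000413), a fold of 4.83.

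The ABC genes ABCA9, ABCA6 and ABCA10 are neighbours on chromosome 17, apart from a pseudogene between ABCA6 and ABCA10 in the annotation, and all 3 rose; ABCA10 and the genes around them were chosen after their values were seen. ABCA9 had 10 reads over the parental libraries and 240 over the Raji/253R libraries, 23.0-fold higher after scaling (95% exact interval 12.3 to 48.6; 37.5-fold without parental replicate a), ABCA6 rose by 1.85 (SE 0.29) and ABCA10 by 1.64 (adjusted p = 0.0364). Genes beside them rose too, PRKAR1A by 0.63, WIPI1 by 1.42, RP11-120M18.2 by 1.42 and the pseudogene by 2.93, while SLC16A6 beyond these fell by 0.71 (adjusted p = 0.0178) and the next family gene, ABCA5, did not pass (difference 0.38, adjusted p = 0.131). ABCC2, an organic anion efflux pump gene, rose by 1.66 (SE 0.29). ABCA2 fell by 2.06 (SE 0.34) and was the family member with the lowest difference. ABCC1, another efflux pump gene, rose from 7.23 ± 0.08 to 7.78 ± 0.09 (adjusted p = 0.0128). Its adjusted p was 0.0624 without parental replicate b, 0.0524 without parental replicate c and 0.0660 without Raji/253R replicate a. By limma with the replicate letter as a block, the adjusted p of ABCC1 was 0.00623. The list of ABC transporters was higher in Raji/253R by camera (adjusted p = 0.00956), with an adjusted p = 0.602 with an estimated correlation and adjusted p = 0.171 among genes of mean log2 CPM of at least 1, 0.183 of at least 3 and 0.101 with array weights. The authors' own ABC sheet holds 29 of these genes with 11 higher and 3 lower; it was chosen on these samples and is not independent evidence. Without parental replicate c 9 family members were called, and without Raji/253R replicate a 8 were. All 3 members on chromosomes 4 and 13 rose, where genes in general were higher in Raji/253R by a median of 0.48 and 0.52, amounts far below the difference of ABCG2. The rises of the other members there were not weighed against that shift, which may add to the count of family members that rose. Without genes of these chromosomes 8 family members rose and 3 fell.

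**Figure D2:**
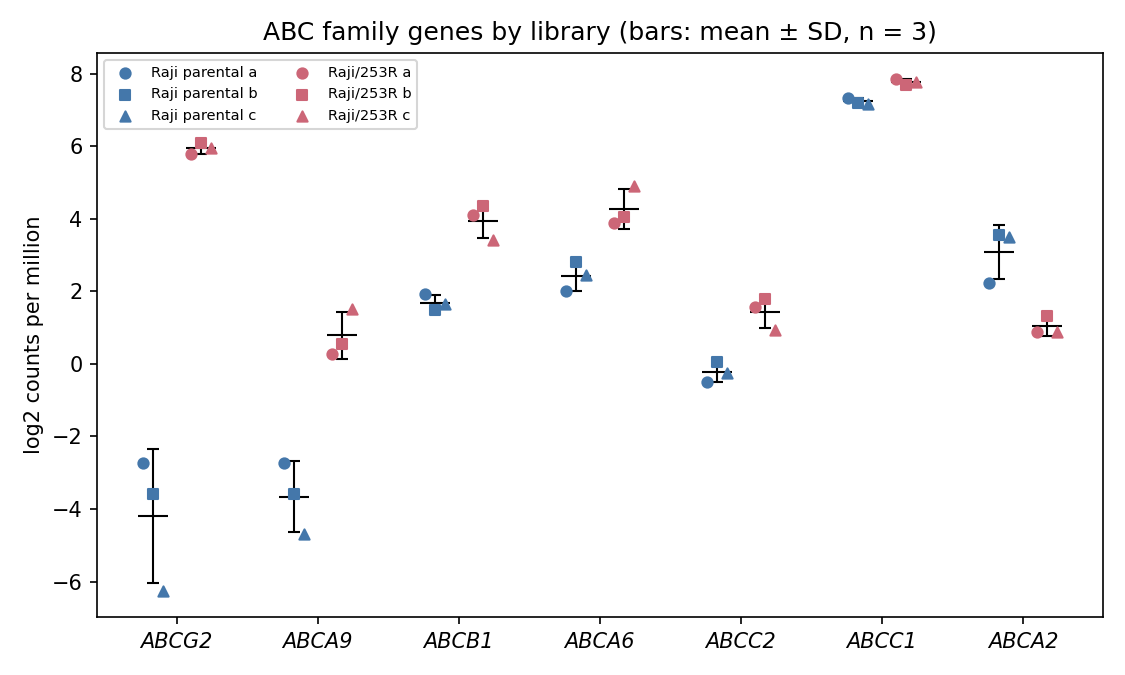
Log2 CPM (vertical axis) of 7 ABC family genes in each library, parental Raji in blue and Raji/253R in red, with circles, squares and triangles for replicates a, b and c and black bars for the mean ± SD of n = 3. ABCG2 lies at 5.95 ± 0.16 in Raji/253R and -4.19 ± 1.85 in the parent, and of the 7 genes ABCA2 is the one that is lower in Raji/253R.

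Many DNA replication and repair genes were lower in the resistant subline, by more in its replicates a and b than in c. Of 193 genes on 8 lists fixed beforehand, 5 rose, 66 fell and 122 did not pass; adjusted over the list alone, 7 rose and 79 fell. Of 52 DNA replication genes 0 rose and 25 fell, and adjusted over the list alone 38 fell. ORC1, a subunit of the origin recognition complex, fell from 5.85 ± 0.17 to 4.34 ± 0.68 (difference -1.51, SE 0.28, adjusted p = 0.00618). TIMELESS, a replication fork protection gene, fell by 1.41 (SE 0.27), and GINS1 and GINS4, subunits of the replicative helicase, had differences of -1.19 (SE 0.23) and -2.06 (SE 0.42). The list was lower by camera (adjusted p = 3.05e-11, median difference -0.74); with an estimated correlation adjusted p = 0.645.

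The replicates of Raji/253R did not share this fall to the same extent. Averaged over the 52 replication genes, the deviation from each gene's mean over all libraries was -0.53 in Raji/253R replicate a, -0.82 in b and 0.19 in c, against 0.44, 0.27 and 0.46 in parental replicates a, b and c. The G2/M list, genes of late cell cycle and mitosis, had -0.25, -0.62 and 0.22 in Raji/253R a, b and c, and 0.33, 0.07 and 0.25 in the parent. Of 44 G2/M genes 0 rose and 9 fell, likewise 9 adjusted over the list alone (camera adjusted p = 5.10e-05; adjusted p = 0.665 with an estimated correlation). MYBL2, a cell cycle transcription factor gene, fell from 8.81 ± 0.22 to 7.17 ± 0.54 (adjusted p = 0.00186), and cyclin B1, CCNB1, fell by 1.30 (SE 0.30), a call lost without Raji/253R replicate a (adjusted p = 0.0547). Of the 193 genes, 13 were called without Raji/253R replicate a, 18 without b and 108 without c, and 37 and 34 without parental replicates b and c.

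**Figure D3:**
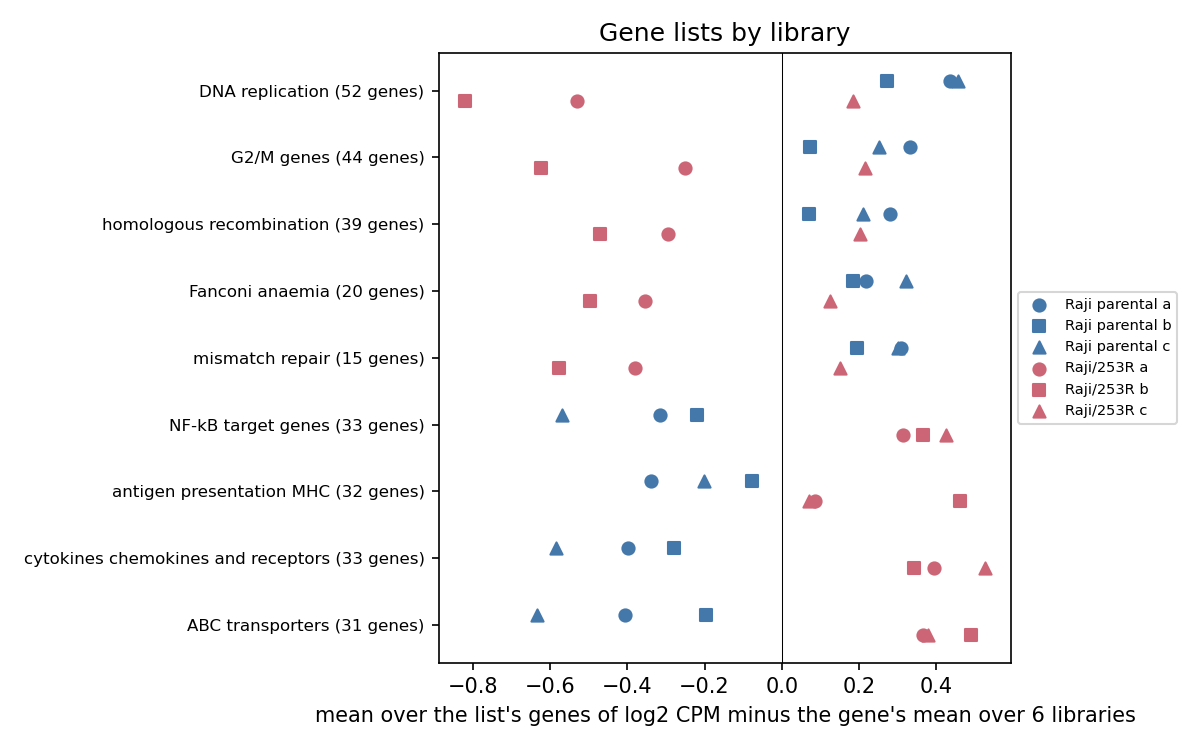
For 9 gene lists (vertical axis, with the number of genes measured), the mean deviation of log2 CPM from each gene's mean over 6 libraries (horizontal axis) in each library, parental Raji in blue and Raji/253R in red, with circles, squares and triangles for replicates a, b and c. For DNA replication Raji/253R replicate c lies at 0.19, nearer to the parental libraries at 0.27 to 0.46, while a and b lie at -0.53 and -0.82.

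In the homologous recombination list Raji/253R replicates a and b lay at -0.29 and -0.47, and c at 0.20 lay within the parental range of 0.07 to 0.28. Of 39 homologous recombination genes 1 rose and 11 fell, and adjusted over the list alone 3 rose and 14 fell (camera adjusted p = 0.00453; adjusted p = 0.665 with an estimated correlation; adjusted p = 0.0520 without Raji/253R replicate b). BRCA1 fell from 6.90 ± 0.24 to 5.70 ± 0.80 (adjusted p = 0.0279). Its adjusted p was 0.0747 without parental replicate a, 0.0567 without parental replicate c, 0.109 without Raji/253R replicate a and 0.0916 without Raji/253R replicate b. By limma with the replicate letter as a block, the adjusted p of BRCA1 was 0.00271. BRCA2, at 5.13 ± 0.20 and 5.33 ± 0.67, did not pass the test (difference 0.21, SE 0.28, adjusted p = 0.632). The damage kinase gene ATM rose by 0.74 (SE 0.14), a call that held without each library in turn.

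Of 20 Fanconi anaemia genes, which act in crosslink repair, 0 rose and 9 fell, and 10 fell adjusted over the list alone (camera adjusted p = 0.00311; adjusted p = 0.645 with an estimated correlation). FANCA fell from 7.65 ± 0.12 to 6.29 ± 0.44 (difference -1.36, SE 0.20, adjusted p = 0.00195) and FANCG by 1.13 (SE 0.23). Of 15 mismatch repair genes 0 rose and 6 fell, and 8 fell adjusted over the list alone (camera adjusted p = 0.00559; adjusted p = 0.645 with an estimated correlation). The DNA ligase gene LIG1, at 7.30 ± 0.18 and 5.88 ± 0.76, fell by 1.42 (SE 0.31), and its adjusted p was 0.0602 without Raji/253R replicate a. Of 20 base excision repair genes 0 rose and 5 fell, the same 5 in number adjusted over the list alone (camera adjusted p = 0.00311; adjusted p = 0.602 with an estimated correlation), among them the glycosylase gene OGG1, at 5.87 ± 0.23 and 4.60 ± 0.69. OGG1 was not called without Raji/253R replicate a (adjusted p = 0.0732) or b (adjusted p = 0.0593). Of 21 DNA damage checkpoint genes 1 rose and 13 fell, and 15 fell adjusted over the list alone (camera adjusted p = 0.000104; adjusted p = 0.645 with an estimated correlation). The phosphatase gene CDC25B fell by 1.22 (SE 0.18) and the ubiquitin ligase gene RNF8 by 0.83 (SE 0.16), both also without each library in turn. In the Fanconi, mismatch, base excision and checkpoint lists, the mean deviations of Raji/253R replicate c were 0.13, 0.15, 0.02 and 0.02. Raji/253R replicate a lay at -0.35, -0.38, -0.24 and -0.31, and b at -0.50, -0.58, -0.37 and -0.44. The lowest parental values were 0.19, 0.19, 0.14 and 0.17.

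The other repair lists did not pass. Of 18 end joining genes 1 rose and 3 fell (camera adjusted p = 0.263), the riser being the ligase gene LIG4 on chromosome 13 with a difference of 1.13 (SE 0.17). Of 24 nucleotide excision repair genes 3 rose and 1 fell (camera adjusted p = 0.803), and DDB2, a damage sensor gene, rose from 6.74 ± 0.41 to 8.15 ± 0.06. Of 23 helicases and binders of G-quadruplexes, four-stranded DNA structures, 1 rose and 5 fell (camera adjusted p = 0.136), the helicase gene RECQL5 being the riser with 0.65 (SE 0.12). Each of these 3 lists had the same counts adjusted over the list alone. The authors' replication and repair sheet holds 31 genes, of which 0 rose and 20 fell here, and their DNA repair sheet holds 18, of which 0 rose and 14 fell. Both sheets were chosen on these samples and are not independent evidence of a direction.

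Chemokine, cytokine and NF-kB target genes were higher in Raji/253R, in all 3 of its libraries. Of 33 cytokines, chemokines and receptors 16 rose and 4 fell, and adjusted over the list alone 18 rose and 5 fell (camera adjusted p = 0.00141; adjusted p = 0.602 with an estimated correlation). CCL5, a chemokine gene, rose from -2.09 ± 0.93 to 3.15 ± 0.17 (difference 5.24, SE 0.41, adjusted p = 5.96e-05), and CXCL9, an interferon-inducible chemokine gene, rose by 2.41 (SE 0.31). Of 33 NF-kB target genes 14 rose and 3 fell, and adjusted over the list alone 16 rose and 4 fell (camera adjusted p = 0.000392; adjusted p = 0.602 with an estimated correlation). TNFAIP3, an inhibitor of NF-kB signalling, rose from 5.55 ± 0.49 to 7.62 ± 0.23, lymphotoxin alpha, LTA, rose by 1.51 (SE 0.17) and the costimulatory gene CD86 by 1.51 (SE 0.18). CCL3 and LTA are among several genes that stand on both lists, so these list results are not independent of each other. The 6 myeloid cell markers, ITGAX among them, moved with these lists, with mean deviations of 0.63, 0.68 and 1.22 in Raji/253R replicates a, b and c and -1.05, -0.31 and -1.17 in the parental ones.

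Antigen presentation genes were also higher. Of 32 measured 12 rose and 1 fell, and adjusted over the list alone 14 rose and 1 fell (camera adjusted p = 0.000496; adjusted p = 0.645 with an estimated correlation). The class II genes HLA-DQA1 and HLA-DQB1 rose from 7.39 ± 0.17 to 8.61 ± 0.35 and from 6.07 ± 0.15 to 7.18 ± 0.35. HLA-DQA2 and HLA-DQB2 had differences of 1.32 (SE 0.18) and 1.58 (SE 0.25), though reads of these paralogs can be assigned to one another. The gene that fell was PSMB9, an immunoproteasome subunit gene, with -0.91; it was named after its values were seen. Interferon-stimulated genes went both ways, 8 of 35 rising and 4 falling, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.0701; 0.0320 with the replicate letter as a block; adjusted p = 0.645 with an estimated correlation): TRIM22 rose by 2.02 (SE 0.25) and OAS1 fell by 1.79 (SE 0.31). Of 22 immediate early genes 4 rose and 1 fell, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.163), with DUSP5, a MAP kinase phosphatase gene, rising by 1.39 (SE 0.19).

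MYC, the oncogene translocated in Burkitt lymphoma, did not pass the test, at 9.52 ± 0.14 in the parent and 9.31 ± 0.26 in Raji/253R (difference -0.21, SE 0.16, adjusted p = 0.363). Of 63 MYC target genes 2 rose and 4 fell, the same counts adjusted over the list alone (camera adjusted p = 0.360): the kinase gene HK2 rose by 0.84 (SE 0.13) and the telomerase gene TERT fell by 1.30 (SE 0.27). Of 12 genes of the MYC network 2 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.539; median difference -0.06, mean 0.12). KLF4 was not among the genes in the table used here. Of 14 KLF factors and CDK inhibitors 5 rose and 2 fell, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0576; 0.0493 with the replicate letter as a block; adjusted p = 0.602 with an estimated correlation). KLF3 on chromosome 4 rose by 1.34 (SE 0.21), CDKN1B (p27), a cell cycle inhibitor gene, rose from 5.17 ± 0.60 to 6.46 ± 0.14, and KLF15 fell by 0.91 (SE 0.19). CDKN1A, which encodes the inhibitor p21, rose from 4.28 ± 0.72 to 5.24 ± 0.21 with an adjusted p of 0.0476. That call was lost without parental replicate a (0.0821) or c (0.0878) and without Raji/253R replicate a (0.104), b (0.112) or c (0.0916), and under other settings. By limma with the replicate letter as a block, the adjusted p of CDKN1A was 0.00759.

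Of 32 BCL2 family and apoptosis genes 7 rose and 4 fell, or 7 and 5 adjusted over the list alone (camera adjusted p = 0.514). BCL2, an apoptosis inhibitor, rose by 1.98 (SE 0.30) and CASP10 by 2.72 (SE 0.33), while the proapoptotic genes HRK and BIK fell by 1.46 (SE 0.15) and 1.20 (SE 0.19).

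Metallothionein and zinc carrier genes were higher in Raji/253R as a list. Of 21 metallothioneins and zinc carriers 9 rose and 2 fell, or 11 and 5 adjusted over the list alone (camera adjusted p = 0.0188; adjusted p = 0.602 with an estimated correlation). The metallothionein genes MT1X and MT2A rose from 1.77 ± 0.21 to 4.74 ± 0.25 (adjusted p = 2.06e-05) and from 4.07 ± 0.05 to 6.67 ± 0.40 (adjusted p = 4.05e-05), though metallothioneins are near-identical paralogs among which reads can be split. The zinc importer gene SLC39A10 rose by 0.96 (SE 0.13). With array weights the list had an adjusted p of 0.0766. Of 19 iron handling genes 0 rose and 3 fell, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.554; median 0.02 with a test direction of down), and ACO1, which encodes iron regulatory protein 1, fell by 0.68 (SE 0.13).

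Stress and detoxification lists did not pass. Of 27 NRF2 target and glutathione genes 3 rose and 7 fell, or 4 and 8 adjusted over the list alone (camera adjusted p = 0.222). SLC7A11, the cystine transporter gene, rose from 6.54 ± 0.19 to 8.04 ± 0.48, and NQO1, a quinone reductase gene, fell by 1.89 (SE 0.29). GSTM1, a glutathione transferase gene with close paralogs, had 173 reads in the parent and 9 in Raji/253R, 20.1-fold higher in the parent after scaling (95% exact interval 10.3 to 44.6), and 30.4-fold without Raji/253R replicate b. Of 12 AHR targets and drug-metabolising enzymes 4 rose and 3 fell, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.783), CYP3A4 having 4 reads in the parent and 49 in Raji/253R, an 11.7-fold higher level (95% exact interval 4.31 to 44.8). Of 31 unfolded protein response genes 3 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.179), and the transcription factor gene XBP1 fell by 0.93 (SE 0.12). Of 18 heat shock protein genes 0 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0707). Of 19 hypoxia targets 3 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0707; 0.0289 with the replicate letter as a block; adjusted p = 0.645 with an estimated correlation), with ANKRD37 on chromosome 4 rising by 1.78 (SE 0.28).

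B cell identity genes went both ways: of 43, 10 rose and 8 fell, or 12 and 14 adjusted over the list alone (camera adjusted p = 0.712). CD27, a costimulatory receptor gene, fell from 8.55 ± 0.08 to 6.87 ± 0.51. CR1, a complement receptor gene, had 273 reads in the parent and 0 in Raji/253R, at least 94.9-fold lower against a floor of 3 reads over the 3 libraries, or at least 61.7-fold lower without Raji/253R replicate c. FCRL4 rose by 2.05 (SE 0.31). Of 27 germinal centre and Burkitt genes 1 rose and 7 fell, or 2 and 11 adjusted over the list alone (camera adjusted p = 0.0281; adjusted p = 0.665 with an estimated correlation). Its call was lost without parental replicate a (adjusted p = 0.0642) and without Raji/253R replicate a (adjusted p = 0.0701) or b (adjusted p = 0.115), without a variance trend (0.0541), at a mean log2 CPM of at least 3 (0.0873) and in protein-coding genes only (0.0845). Its mean deviation was -0.34 and -0.45 in Raji/253R replicates a and b but 0.29 in c, above the parental libraries at 0.10 to 0.26. MME, the CD10 gene, fell by 1.26 (SE 0.21) and LMO2 rose by 1.98 (SE 0.42). Of 15 plasma cell genes 1 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.113), SLAMF7 rising by 2.31 (SE 0.22) and PRDM1 falling by 1.25 (SE 0.26).

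Markers of other cell types were measured as a check. Of 6 myeloid markers 2 rose and 0 fell, also adjusted over the list alone: ITGAX, as above, and CSF1R with 14 reads in the parent and 116 in Raji/253R, a ratio of 7.94 with a 95% exact interval of 4.55 to 14.98, or 12.2 without parental replicate b (camera adjusted p = 0.0188; adjusted p = 0.602 with an estimated correlation). That list was not called without parental replicate a (adjusted p = 0.0541) or Raji/253R replicate c (adjusted p = 0.0859), nor with array weights (0.111). The other 2 of its 4 leading members, ITGAM and CD33, had 29 and 17 reads in the parent and 82 and 46 in Raji/253R, ratios of 2.71 (95% exact interval 1.76 to 4.29) and 2.59 (1.46 to 4.83), and did not pass the limma test. Most of their Raji/253R reads came from replicate c, without which the ratios were 1.58 and 1.47, and without parental replicate b that of ITGAM was 4.72. Of 7 T and NK cell markers 2 rose and 3 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.515), NKG7 rising by 1.98 (SE 0.39) and TCF7 falling by 2.39 (SE 0.36). Of 7 epithelial and stromal markers 1 rose and 1 fell, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.382), COL1A1 rising by 2.14 (SE 0.43) and VIM falling by 1.83 (SE 0.35). The single erythroid marker measured, EPOR, fell by 1.15 (SE 0.22).

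Cytosolic ribosomal protein genes were slightly higher in Raji/253R replicates a and b, with mean deviations of 0.08 and 0.33, and not in c, at -0.02 where the parental libraries lay at -0.31, -0.08 and 0.00. Of 80 genes 8 rose, where 1850 of 17391 did over all genes, and 0 fell, or 7 and 0 adjusted over the list alone (camera adjusted p = 4.56e-05, median difference 0.26; adjusted p = 0.665 with an estimated correlation). RPL34 on chromosome 4 rose from 8.31 ± 0.10 to 9.14 ± 0.22 and RPL22 by 0.69 (SE 0.13). RPL21 on chromosome 13 rose by 0.98 (SE 0.17), though it has many processed pseudogenes. Of the 8, 3 lie on chromosomes 4 and 13. Metabolic lists did not pass: of 76 nuclear oxidative phosphorylation genes 4 rose and 3 fell, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.956). Of 24 glycolysis genes 2 rose and 1 fell (camera adjusted p = 0.801; median -0.07, mean 0.03), and of 29 cholesterol synthesis genes 1 rose and 1 fell (camera adjusted p = 0.555), with the same counts in both lists adjusted over the list alone. Of 13 mitochondrial genome transcripts 0 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.183), and these transcripts took 5.77% of the reads of parental replicate c against 2.25% to 3.61% in the other 5 libraries.

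Replication-dependent histone genes, whose main transcripts lack a poly(A) tail, split by direction. Of 38 measured 8 rose and 17 fell, or 9 and 21 adjusted over the list alone (median -0.92; camera adjusted p = 0.00690 for a lower level; adjusted p = 0.602 with an estimated correlation). HIST1H1E fell from 1.83 ± 0.46 to -1.53 ± 0.10 and HIST1H1B fell from 428 reads in the parent to 22 in Raji/253R, a ratio of 20.3 (95% exact interval 13.2 to 32.7; 36.3 without Raji/253R replicate c), while HIST1H2BK rose by 2.07 and HIST1H2AC by 2.03. HIST1H2BK and HIST1H2AC were chosen after their values were seen. The list turned higher in Raji/253R among genes with a mean log2 CPM of at least 1 (adjusted p = 5.92e-05) and of at least 3 (adjusted p = 0.000569), and in direction among protein-coding genes only (adjusted p = 0.495). Its call was lost without Raji/253R replicate c (adjusted p = 0.0691).

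The authors' deposited tables of enriched terms list DNA replication terms as down and translation pathways as up. Of their gene ontology terms 36 are listed as down and 5 as up, and of their pathways 94 as down and 27 as up. The ontology terms with the smallest false discovery rates (FDR) in the authors' deposited table are DNA strand elongation involved in DNA replication with 35 genes and DNA strand elongation with 38, both down with FDR 1.41e-07, followed by DNA replication initiation with 33 genes (FDR 9.28e-06). Among terms listed as up, regulation of interleukin-4 production has an FDR of 0.0207 and the interferon-gamma-mediated signaling pathway one of 0.0380. Their pathway table is led by DNA strand elongation (32 genes, down, FDR 1.53e-07) and activation of the pre-replicative complex (30 genes, down, FDR 1.04e-06). Its first pathway listed as up is peptide chain elongation, with 78 genes and FDR 9.86e-05. The authors' top genes sheet holds 19 genes here, all of which rose; ABCG2, BCHE, AK8 and CCL5 had the smallest p of these. BCHE, the butyrylcholinesterase gene, had 1 read in the parent and 397 in Raji/253R, 381-fold higher after scaling (95% exact interval 67.9 to 15069). The BCHE ratio was 248 without parental replicate a and at least 83.8 without parental replicate b, which held the 1 read. AK8, an adenylate kinase gene, had 8 and 452 reads, 54.2-fold higher in Raji/253R (95% exact interval 27.3 to 126). Their curated sheet holds 694 genes, of which 693 rose here; TXNIP, a thioredoxin-binding protein gene, rose from 7.03 ± 0.15 to 9.40 ± 0.27. These sheets were chosen on these samples and are not independent evidence.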

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

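Voom weights, the authors' own test, leaving out chromosomes 4 and 13, and protein-coding genes only were chosen after the results were seen. The direction of every named gene that was called held under all alternatives run, and for named genes 3050 results kept their side of the threshold, 347 lost it and 37 gained it. Both scalings, quantile normalization and median-centred libraries, kept all 16 gene list calls and moved no count past 1.5 times, with 2178 genes higher and 1428 lower in median-centred libraries against 1850 and 1685 as reported. Quantile normalization called further lists, 21 in all. With each library left out in turn, differing genes ranged from 1523 to 4680, higher ones from 902 to 2210, lower ones from 621 to 2470, those with at least 2-fold difference from 1079 to 2302, ABC family calls from 8 to 15, replication and repair calls from 13 to 108 and those lower in Raji/253R from 9 to 102. The lowest values all came without Raji/253R replicate a, and the highest all came without Raji/253R replicate c; the cause was not tested. With a minimum mean log2 CPM of 1, 1173 genes were higher and 782 differed at least 2-fold; with a minimum of 3, 1924 differed, 874 higher and 1050 lower, 443 at least 2-fold, and 7 of the ABC family, since fewer genes are tested. Without a variance trend 2351 differed, 1023 lower, with 25 replication and repair calls, 20 of them lower; with array weights 7506 differed, 3624 higher and 3882 lower, with 122 and 107; the cause was not tested. At a threshold of 0.01, 1265 differed, 733 higher and 532 lower, 966 at least 2-fold, 8 of the ABC family and 13 of replication and repair, 10 of them lower. By Holm adjustment of the limma test 1.4e+02 genes differed, 70 higher and 72 lower, and as many, 1.4e+02, differed at least 2-fold, with 1 of the ABC family and 0 of replication and repair, 0 of those lower, where 108 had an unadjusted p under 0.05. Tested against 2-fold by treat, 298 genes passed. The replicate letter as a block gave 4969 differing genes and 20 gene lists; besides 4 lists and the genes NFS1, MXD3, MGA, HSPA1B, ACTA2, FDFT1 and LSS newly called, it changed no other call of a list or named gene. With an estimated correlation camera called 0 lists, 1 having an unadjusted p under 0.05, and fry called 7, 5 of them among the 16 reported, testing whether a list moves one way without comparing it with other genes. By fry no list of DNA replication, G2/M or repair genes passed, with an FDR of 0.156 for DNA replication and 0.276 for G2/M genes. The lists of ABC transporters (0.0586), antigen presentation (0.156) and cytosolic ribosomal proteins (0.225) did not pass fry either. The histone list reversed to higher with a minimum mean log2 CPM of 1 (adjusted p = 5.92e-05) and of 3 (0.000569), and in protein-coding genes only (0.495), where fewer of its members are tested; the cause was not tested further. Alternatives foreseen for counts or unlogged values (edgeR and DESeq2 normalization, count filters, another pseudocount) were not run, since the values are log2. The 3 libraries per line and the smallest read total, 39265667, limit what can be called: in simulated data 30% of genes changed 1.5-fold were found. Far fewer genes changed in the simulation than were called here, which makes the adjusted threshold stricter there. That share of 30% need not hold for the real comparison.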

Other observations

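Of the tests below, that of RNA polymerase II transcripts, that of parental cells in a library and the permutation of letters kept together were chosen only after the result was seen, and so were the genes STS, HDHD1, HTATIP2 and SDR42E1 and the neighbours named. Several well-expressed parental genes were all but absent in Raji/253R. HDHD1, a phosphatase gene that lies beside STS on the X chromosome, had 2914 reads in the parent and 6 in Raji/253R, 507-fold higher in the parent after scaling to library size (95% exact interval 232 to 1382), and the neighbours on either side of this pair, the pseudogene RP11-459A10.1 and PNPLA4, had differences of 0.03 and 0.10 that did not pass. HTATIP2 on chromosome 11 had 2777 and 2 reads, a ratio of 1448 (95% exact interval 401 to 11967), with its neighbours NAV2 and PRMT3 at -0.53 and 0.35, neither passing. SDR42E1 on chromosome 16 had 902 reads in the parent and 0 in Raji/253R, at least 314-fold lower against a floor of 3 reads over the libraries, or at least 204-fold lower without Raji/253R replicate c. Of the 8 measured genes nearest to ABCG2 on chromosome 4, PYURF rose by 0.79, SPARCL1 and PPM1K fell by 3.80 and 0.65, and the other 5 did not pass, PKD2 beside it having a difference of 0.18.

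Genes of chromosomes 4 and 13, which held 18.2% of the genes that rose against 5.68% of those tested, were higher in Raji/253R. Over 9690 protein-coding genes of mean log2 CPM of at least 1, the 339 genes of chromosome 4 had a median difference of 0.48 with 84.1% above 0, and the 176 of chromosome 13 a median of 0.52 with 81.8% above 0; over all other genes the shift was 0.56 and 0.59, and it was between 0.39 and 0.64 in each of the 3 pairs of libraries. In 10000 random sets matched on expression the two-sided p was 0.0002 for both, the smallest they can give (adjusted p = 0.000767 over 23 chromosomes); 8 other chromosomes also had an adjusted p under 0.05, with shifts between -0.18 and 0.10. After a loess on GC content the lower of both shifts was 0.50, and after one on transcript length 0.55, so neither trend removed it. Split in 3 parts by gene order, each part of both chromosomes was shifted, the lowest by 0.50, which is consistent with extra copies of both chromosomes in the resistant line, where 3 copies in place of 2 would give 0.58; DNA was not analysed here, and a copy gained during selection remains a hypothesis.

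Of 8 entries for RNAs without a poly(A) tail assigned to RNA polymerase II, 6 fell in Raji/253R and 1 rose (median -2.44), of 7 assigned to RNA polymerase III 5 fell (median -2.42), and both ribosomal RNAs of polymerase I fell (median -1.88). For small nuclear RNAs the polymerase was taken from the gene name, and some entries, such as RNU2-59P and RNU6-1223P, are named as pseudogenes. Reads can be split among copies of such RNAs, so these are counts of entries and not of distinct transcripts. Since products of all 3 polymerases were lower together, less carry-over of untailed RNA into the Raji/253R libraries may account for these falls, RPPH1 and RMRP among them, though carry-over and line cannot be separated by design and a biological fall of these RNAs was not tested. Within the lines, libraries with more untailed RNA also had more replication-dependent histone transcript: the correlation of deviations from the line means over 6 libraries was 0.941 (Spearman 0.943), with an exact one-sided p = 0.167 for both over the 6 permutations that keep same-letter libraries together, the smallest they can give, against 0.0278 over 36 permutations that ignore the letters. Without the farthest libraries, replicate b of each line, r was 0.532, so the relation rests on those and does not settle whether carry-over lowered the histone transcripts. Lower replication as the source of the histone falls was not tested by itself. Raji/253R replicate c had the lowest mean deviation of the histone list, -0.55, where its replication genes lay at 0.19. It also had the least untailed RNA of its line, with a deviation of -0.33 against -0.14 in a and 0.48 in b. The histone value of that library therefore cannot tell lower replication from less carry-over.

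Raji/253R replicate c lay nearer to the parental libraries in replication genes than replicates a and b. On a scale where 0 is the parental mean and 1 the mean of a and b, the 68 replication and G2/M genes called without replicate c had a median of 0.18 in c, and the other 4612 genes called without it one of 0.60, a difference of 0.42. Parental cells in that library would need a share of 74.7% to give the level of these genes, but STS, HDHD1, HTATIP2 and SDR42E1 together had 5 reads in c where the parental level would give 6202, an upper 95% limit of 0.188%, which argues against them. A different growth state of that culture is consistent with the difference of 0.42, found and tested on the same libraries, so the lower replication and repair genes may in part reflect how replicates a and b were growing and not resistance itself; no record of growth was analysed here.

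The 6 libraries can be split 10 ways into 3 and 3, too few for a share under 0.05. Every split but the real one puts libraries of both lines on each side, so the line difference adds to the spread within its groups. Gene counts of 0 from those splits are therefore built in and do not argue against chance. As many differing genes as the 3535 between the lines came from 1 split, the real one, and the highest of the others by limma was 0, with between 63 and 1914 genes at an unadjusted p under 0.05. Likewise 1 split gave as many as the 1725 genes with at least 2-fold difference, the 14 ABC family calls and the 71 replication and repair calls, the highest of the others being 0 in each case. For gene lists 2 splits gave 16 or more: the real one with 16, and that of parental a and c with Raji/253R a against the rest with 17, which parts 1 pair of letters. Among the 3 other splits that part all 3 pairs as the real one does, the highest gave 13 lists. Every split other than the real one called between 5 and 17 lists by camera, while calling 0 genes. At the preset correlation the number of lists called therefore does not set the real split apart from groupings that mix the lines.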
